A study of Mus musculus with 8 samples.

How the data were processed

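RNA of mouse colon fibroblasts was sequenced in 8 libraries. Per the labels' protocols, the cells came from the C57BL6/J strain, grew on tissue culture plastic in Advanced DMEM F12 with 10% FBS and received medium conditioned by APTKA, a name that the labels do not expand. One group of 4 libraries came from cells that were not irradiated, and the other group of 4 from cells given 3 fractions of 2 Gy. Both groups were collected 72 h after the first dose. The replicate numerals I to IV were taken from the sample titles. The design text calls the samples independent, but the labels do not say whether they came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

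The values were deposited by the authors as raw whole-number read counts per Ensembl gene, with 1 file per library and no normalization. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, STAR 2.5.2a and featureCounts 1.5.0-p1 with the mm10 build. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes that share sequence with near copies, such as histones, Mx2, H2-Q4, Abca8a and Pgk1, therefore carry some uncertainty, as do genes that overlap another gene on either strand. Per the labels, the molecule was polyA RNA extracted with a Qiagen RNeasy mini kit.

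Each file listed 55573 genes. Symbols and coordinates came from GENCODE M21, which annotates the GRCm38 assembly and shares its coordinates with mm10. A symbol was found for 55394 identifiers, and the 179 without one held 0.0223% of the counts. Total counts ran from 28731227 to 37157216 per library. A gene without counts in 1 library of this depth is compatible with up to 3 counts, which covers counting error only.

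Counts were tested with edgeR 4.0.16 in R 4.3.3. Normalization used TMM factors, and filterByExpr with its minimum count of 10 and minimum total of 15 kept 15259 genes and left out 40314. The quasi-likelihood test of irradiated against non-irradiated libraries used all 8 libraries with group as the sole term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The log2 fold change is irradiated over non-irradiated, and its SE was derived from the fold change and the F statistic. Levels are CPM, counts scaled to the library size, computed from the deposited counts with the TMM factors. They are given as mean ± SD over the 4 libraries of a group. Single-library CPM of mitochondrial transcripts, rRNA loci, Rn7sk, Lars2, Cebpb and Scand1 were instead scaled to total counts without the TMM factors.

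The 18 functional gene lists, the 8 cell type marker lists, the tests and the rule for named genes were set before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 5 CPM in the higher group, no overlap of the groups and an established symbol. It added, from each functional list, the 2 members with the smallest adjusted p and the 1 further member with the highest mean CPM, and a fixed set of genes of interest named whatever their values. Members beyond this rule were chosen after their values were seen, and a few genes that the rule takes are not reported here. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 18 lists. Camera with an estimated correlation and fry, which tests whether a list moves one way on balance, were run beside it. List members were counted by the calls over all genes and by p-values adjusted over the list alone.

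The pipeline was tested on simulated counts drawn from the means and library sizes of these samples, with 50 genes changed at each of 4 fold sizes. For this comparison it recovered 66% of the genes changed 1.3-fold, 82% at 1.5-fold, 94% at 2-fold and 100% at 4-fold among 15074 genes tested, with 12 unchanged genes called. None of 20 random lists was called there. The simulated genes varied independently of one another, whereas the estimated correlation within the real lists reached 0.57. The simulation therefore does not show how often such lists are called by chance.

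Alternatives set beforehand were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter beyond a count in 1 library, at least 1 CPM in 4 libraries, a threshold of 0.01, the replicate numeral as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were an offset for each library's trend on transcript GC content and length (loess with span 0.5, available for 15249 of the tested genes), leaving out irradiated libraries I and II, and leaving out non-irradiated libraries I and III.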

Results

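The study title concerns inflammatory fibroblasts and resistance to neoadjuvant therapy in rectal cancer, and the samples ask what fractionated irradiation changes in colon fibroblasts already exposed to conditioned medium. Polyadenylated RNA, by its label, was counted per gene in 4 non-irradiated libraries with 28731227, 31164992, 37157216 and 31514565 counts and in 4 irradiated libraries with 36497990, 33386941, 36346312 and 30203137 counts (replicates I to IV in each case). Most fibroblast identity markers were abundant: Col1a2, a chain of type I collagen, stood at 5350 ± 339 CPM, Vim (vimentin) at 1120 ± 26.0 CPM and Pdgfra, a receptor of mesenchymal cells, at 973 ± 31.5 CPM in non-irradiated libraries (SD, n = 4). Of the 11 markers, S100a4 (3.27 CPM), Fap (3.92 CPM) and Lum (5.44 CPM) were low there. The others were at 112 CPM (Pdpn) or higher. The labels name no batch. In counts, irradiated I and II differed by a chi-square per degree of freedom of 5.5 and III and IV by 5.1, against 16 to 27.6 for the other irradiated pairs, and non-irradiated pairs ranged from 5.3 to 13.9. Since no pair agreed within counting noise, none was treated as 1 library deposited again. This does not show that the libraries came from separate cultures. The 12S and 16S mitochondrial rRNA together took 15129 and 15263 CPM in irradiated I and II and 4179 to 5934 CPM in the other 6 libraries.

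Irradiated fibroblasts held fewer transcripts of cell division genes and more transcripts of p53 target genes, with most fold changes small. Of 15259 genes tested, 395 were higher and 634 lower in irradiated cells at an adjusted p under 0.05, and 22 and 7 of these changed at least 2-fold. Few of the genes at 2-fold had at least 5 CPM in the higher group, no overlap of the groups and an established symbol. These were Anxa8 and Ano3 among the higher and Pbk, Kntc1 and Dlgap5 among the lower genes. The called genes had a median absolute log2 fold change of 0.30, and 82.2% of them changed less than 1.5-fold. The CPM of the groups did not overlap for 2167 genes (14.2%), where chance gives 2.86%. The count of higher genes dropped to 257 without non-irradiated I, 234 without irradiated III and 221 without irradiated IV, and the count of lower genes to 415 without irradiated IV and to 295 without both irradiated I and II, a setting chosen after seeing the data. At 2-fold, lower genes numbered 4 without non-irradiated II and 16 without non-irradiated III, and higher genes 14 with DESeq2 and 12 among genes with at least 1 CPM in 4 libraries. Other settings raised the counts, to 648 higher genes without a filter and 608 with the GC and length trends removed. Higher genes at 2-fold numbered 51 without a filter and 34 without both irradiated I and II. Lower genes at 2-fold numbered 14 without a filter and 30 without both non-irradiated I and III.

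Anxa8, a calcium-dependent phospholipid-binding annexin, rose most among called genes with at least 5 CPM in the higher group, no overlap of the groups and an established symbol. It went from 3.13 ± 0.315 to 9.16 ± 0.247 CPM (SD, n = 4 each), 2.92-fold (log2 fold change 1.54, SE 0.09, adjusted p = 1.33e-06). Its gene (ENSMUSG00000021950) lies on chromosome 14 from 34085981 to 34100571 of mm10 and is protein-coding. Ano3, a member of the anoctamin family (ENSMUSG00000074968, chromosome 2, 110655201 to 110950923), rose from 8.03 ± 0.702 to 18.3 ± 0.942 CPM (log2 fold change 1.19, SE 0.07, adjusted p = 1.39e-06). Further rises were seen for Cpz, a carboxypeptidase (log2 fold change 0.95, adjusted p = 6.51e-05), Slit1, an axon guidance ligand (0.94, 0.000252), Hmcn2, an extracellular hemicentin (0.87, 2.89e-05), Abca8a, a membrane transporter (0.86, 0.000331), Svop (0.80, 0.000467) and the zinc finger gene Zfp456 (0.77, 0.000741). Except for Hmcn2 at 29.2 ± 3.51 CPM and Ano3, these genes stayed under 10 CPM in irradiated cells. All 8 calls were kept whichever single library was left out.

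Under the same limits, the 8 genes with the largest falls were mostly genes of mitosis and cytokinesis. Pbk, a mitotic kinase (ENSMUSG00000022033, chromosome 14, 65805837 to 65817822), went from 7.67 ± 1.15 to 3.63 ± 0.306 CPM (log2 fold change -1.07, SE 0.12, adjusted p = 8.94e-05; SD, n = 4). Kntc1, a kinetochore component (ENSMUSG00000029414, chromosome 5, 123749716 to 123821593), went from 47.3 ± 4.53 to 22.9 ± 1.04 CPM (log2 fold change -1.05, SE 0.06, adjusted p = 1.39e-06), and its partner Zwilch fell with a log2 fold change of -0.87 (adjusted p = 6.51e-05). Dlgap5, a spindle protein, fell with a log2 fold change of -1.01 (adjusted p = 1.08e-05), Anln (anillin, which organises the cleavage furrow) with -0.98 (1.15e-05), the formin Diaph3 with -0.93 (6.04e-05), Iqgap3 with -0.89 (1.32e-05) and the mitotic cyclin Ccnb2 with -0.87 (0.000357).

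The lists of dividing cells fell as groups. All 35 tested G2/M and mitosis genes were called lower, with log2 fold changes from -1.01 to -0.40 and a median of -0.65, and the same 35 were lower when adjusted over the list alone. Mki67, the proliferation marker, went from 105 ± 14.8 to 58.2 ± 2.49 CPM (log2 fold change -0.85, SE 0.08, adjusted p = 3.93e-05; SD, n = 4; chromosome 7, 135689784 to 135716361). Cdc20, an activator of the anaphase-promoting complex, fell from 29.4 ± 1.17 to 18 ± 1.04 CPM (log2 fold change -0.71, adjusted p = 1.15e-05), and Top2a, topoisomerase II alpha, from 149 ± 18.6 to 101 ± 1.74 CPM (log2 fold change -0.55, adjusted p = 0.000298). Of 33 G1/S and replication genes, 21 were lower and 0 higher (24 lower when adjusted over the list alone), with a median of -0.34. Mcm3, a subunit of the replicative helicase, fell from 52.4 ± 1.45 to 34.7 ± 1.3 CPM (log2 fold change -0.60, adjusted p = 5.18e-06) and Pole, the catalytic subunit of DNA polymerase epsilon, from 42.4 ± 2.78 to 26.3 ± 1.43 CPM (-0.69, 1.32e-05), while Rrm1, the large subunit of ribonucleotide reductase, did not pass the test (192 ± 12.6 and 183 ± 7.27 CPM, log2 fold change -0.07, adjusted p = 0.477). Camera gave an adjusted p = 2.75e-43 for the G2/M list and 2.19e-17 for the G1/S list at the preset correlation. With an estimated correlation, adjusted p = 0.0504 for G2/M, which misses the threshold, and adjusted p = 0.0413 for G1/S. Lmnb1, the lamin B1 gene, was at 19.4 ± 0.462 and 17.1 ± 0.771 CPM (log2 fold change -0.18, adjusted p = 0.0605) and Hmgb2, a chromatin protein, at 4.43 ± 0.606 and 3.62 ± 0.481 CPM (log2 fold change -0.29, adjusted p = 0.197), neither of which was called, although Lmnb1 passed with the GC and length trends removed (0.0395), a setting chosen after seeing the data.

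**Figure D1:**
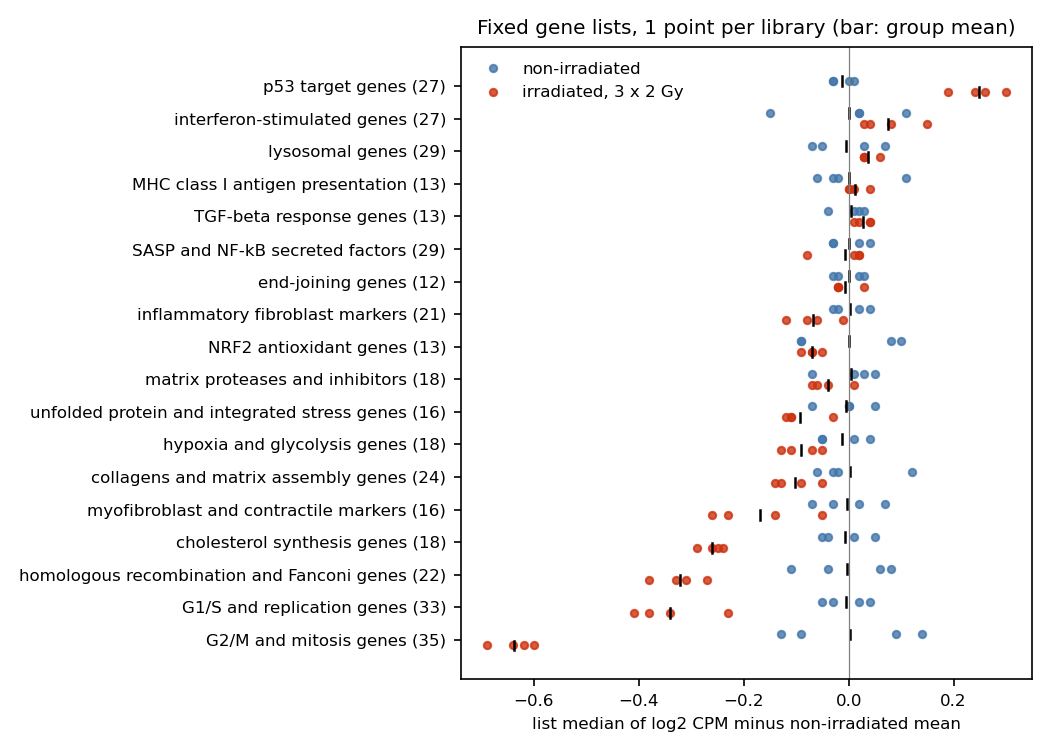
For each of the 18 functional lists (tested members in parentheses), the horizontal axis gives the median over members of log2 CPM minus the non-irradiated mean, with 1 point per library and a bar at each group mean. The 4 irradiated libraries lie between -0.69 and -0.60 for G2/M and mitosis genes and between 0.19 and 0.30 for p53 target genes, apart from all non-irradiated libraries.

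Transcripts of p53 target genes rose. Of 27 tested, 15 were higher and 0 lower, with a median log2 fold change of 0.25. Trp53inp1, a p53-induced nuclear protein, went from 660 ± 31.4 to 956 ± 25.0 CPM (log2 fold change 0.53, SE 0.04, adjusted p = 1.08e-05; SD, n = 4; chromosome 4, 11156431 to 11174379). Ccng1 (cyclin G1) went from 1080 ± 48.6 to 1450 ± 26.3 CPM (log2 fold change 0.42, SE 0.04, adjusted p = 3.21e-05). Mdm2, the ubiquitin ligase that targets p53, went from 1130 ± 29.8 to 1410 ± 35.3 CPM (log2 fold change 0.33, SE 0.04, adjusted p = 9.95e-05; chromosome 10, 117688875 to 117710758). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, went from 430 ± 34.6 to 544 ± 21.9 CPM, 1.27-fold (log2 fold change 0.34, SE 0.05, adjusted p = 0.00135; chromosome 17, 29090976 to 29100727). Bbc3, a pro-apoptotic gene, had the largest rise of the list (log2 fold change 0.65), and Btg2 and Dcxr each rose with 0.44. Adjusted over the list alone, 19 were higher and 1 was lower, Zmat3 (log2 fold change -0.21). Camera gave an adjusted p = 1.56e-14, and adjusted p = 0.0323 with an estimated correlation. The p53 gene itself, Trp53, was at 79.4 ± 8.95 and 76.2 ± 2.43 CPM (adjusted p = 0.666). The senescence-associated inhibitors Cdkn2a (21.9 ± 1.75 and 23.9 ± 1.68 CPM, adjusted p = 0.325) and Cdkn2b (4.31 ± 0.426 and 5.42 ± 0.749 CPM, adjusted p = 0.109) were not called, although Cdkn2b passed with an adjusted p = 0.0435 without both irradiated I and II, a setting chosen after seeing the data.

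Some genes of homologous recombination and the Fanconi pathway were lower, and few end-joining genes were called. Of 22 recombination and Fanconi genes, 11 were lower and 0 higher (12 lower when adjusted over the list alone), with a median of -0.30. Brca1 fell from 25.8 ± 1.86 to 18.3 ± 0.871 CPM (log2 fold change -0.50, adjusted p = 0.000279; SD, n = 4) and Rad51ap1, a recombination factor, from 9.34 ± 1.11 to 5.49 ± 0.404 CPM (-0.76, 0.00029), while Rad50, part of a break-sensing complex, did not pass the test (156 ± 3.64 and 161 ± 4.12 CPM, adjusted p = 0.474). The list had an adjusted p = 2.47e-09 by camera, and adjusted p = 0.161 with an estimated correlation, which loses the call. Of 12 end-joining genes 1 was called, the DNA polymerase gene Polm (log2 fold change -0.30, adjusted p = 0.0171), and without irradiated IV its adjusted p was 0.0588. Dclre1c (Artemis; log2 fold change 0.15, adjusted p = 0.274) and Trp53bp1 (132 ± 4.06 and 132 ± 1.61 CPM, adjusted p = 0.979) were not called, the count adjusted over the list alone was also 1 lower and 0 higher, and the list had an adjusted p = 0.624.

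**Figure D2:**
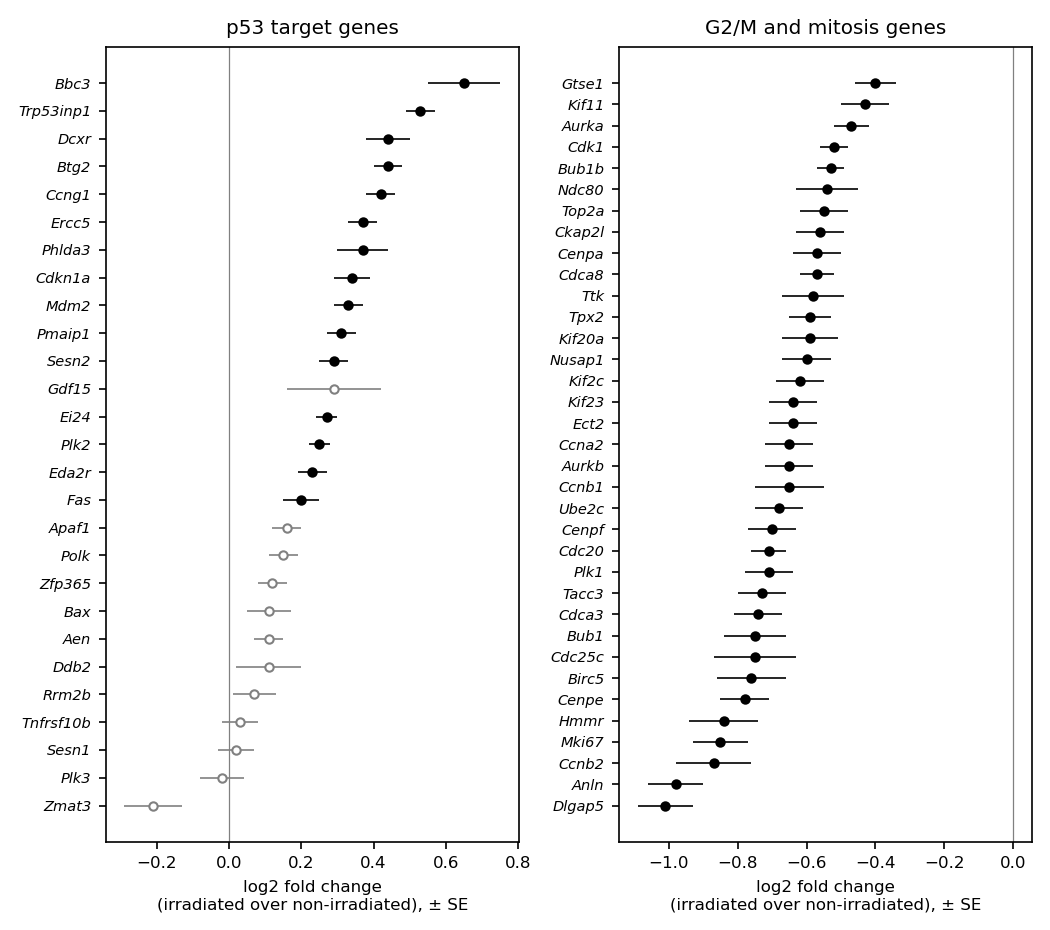
Log2 fold changes (irradiated over non-irradiated, horizontal axis) ± SE of each tested member of 2 lists, with filled points for genes called at an adjusted p under 0.05 and open points for the others. All 35 G2/M genes lie below 0 and are filled. Of 27 p53 targets, 15 are filled, and these lie above 0.

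Inflammatory and secreted factors moved in both directions or not measurably. Of 29 SASP and NF-kB secreted factors tested, 3 were higher and 3 lower (4 and 5 when adjusted over the list alone). Icam1, an adhesion molecule, rose from 11.6 ± 0.753 to 15.8 ± 1.63 CPM (log2 fold change 0.46, SE 0.08, adjusted p = 0.00387; SD, n = 4), whereas Serpinb2, a plasminogen activator inhibitor, fell from 94.8 ± 6.32 to 78.2 ± 4.16 CPM (-0.28, 0.00643). Csf1, the macrophage growth factor, was at 2260 ± 41.9 and 2470 ± 71.3 CPM (log2 fold change 0.13, adjusted p = 0.048), a call kept in 1 of the 8 fits that leave out 1 library, that without non-irradiated I, with adjusted p up to 0.127 in the others. The list had an adjusted p = 0.904 by camera, with a median of -0.02 and a mean of 0.00. Il6 was at 10.2 ± 1.79 and 9.90 ± 1.05 CPM (log2 fold change -0.05, SE 0.11, adjusted p = 0.854), Cxcl1 at 74.0 ± 5.65 and 73.9 ± 3.31 CPM (log2 fold change 0.00, SE 0.06, adjusted p = 0.985) and Il1a at 18.2 ± 0.419 and 20.1 ± 1.17 CPM (log2 fold change 0.14, SE 0.06, adjusted p = 0.173). The interleukin 1 antagonist gene Il1rn had 4 counts over all libraries and was not tested.

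Of 21 inflammatory fibroblast markers, 1 was higher and 3 lower (2 and 4 when adjusted over the list alone), and the list had an adjusted p = 0.176. Ptgs2, the inducible cyclooxygenase, rose from 1410 ± 146 to 1740 ± 77.1 CPM (log2 fold change 0.30, adjusted p = 0.00995; SD, n = 4). Its call was lost without both irradiated I and II (0.105) and without both non-irradiated I and III (0.0529), settings chosen after seeing the data. The interleukin 1 receptor gene Il1r1 fell from 114 ± 1.91 to 98.7 ± 2.82 CPM (-0.20, 0.0045). The chemokine gene Cxcl12 was at 316 ± 17.5 and 280 ± 7.15 CPM (log2 fold change -0.17, adjusted p = 0.0249). The call of Cxcl12 was lost, with adjusted p up to 0.0834, without any 1 of non-irradiated I and IV and irradiated I, II and III. Pdgfra did not change measurably (log2 fold change -0.03, SE 0.04, adjusted p = 0.674).

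Some contractile and matrix genes were lower. Of 16 myofibroblast and contractile markers, 5 were lower and 0 higher (10 lower when adjusted over the list alone), with a median of -0.17. Postn (periostin) fell from 928 ± 54.8 to 790 ± 15.7 CPM (log2 fold change -0.23, SE 0.04, adjusted p = 0.00492; SD, n = 4) and Mylk, the myosin light chain kinase, from 104 ± 5.62 to 88.6 ± 4.42 CPM (-0.23, 0.0118). Acta2, smooth muscle actin, was at 362 ± 18.5 and 305 ± 33.4 CPM (log2 fold change -0.25, SE 0.07, adjusted p = 0.0402). The call of Acta2 was lost without any 1 of non-irradiated I, II and IV and irradiated II and IV, with adjusted p up to 0.116. Of 24 collagens and matrix assembly genes, 7 were lower and 0 higher (11 lower when adjusted over the list alone), with a median of -0.12. Fbln1 (fibulin 1) fell from 43.2 ± 2.22 to 32.8 ± 1.52 CPM (log2 fold change -0.40, adjusted p = 0.000272) and Sparc (osteonectin) from 715 ± 9.23 to 582 ± 28.0 CPM (-0.30, 0.000357). Col3a1 (6100 ± 786 and 5570 ± 200 CPM, adjusted p = 0.319) and Col1a1 (2080 ± 199 and 1810 ± 227 CPM, adjusted p = 0.172) were not called, and the groups overlapped for both. They passed without the low-count filter, with adjusted p = 0.0162 for Col3a1 and 2.77e-05 for Col1a1. Their log2 fold changes stayed at -0.13 and -0.20 there, and the cause of the lower adjusted p was not tested. Col1a1 also passed without both irradiated I and II (0.0235). The matrix protein gene Tnc, not called (adjusted p = 0.155), passed without non-irradiated III (0.0344) and without both non-irradiated I and III (0.0286). Camera gave an adjusted p = 3.66e-05 for the contractile list and 0.000284 for the collagen list, and with an estimated correlation adjusted p = 0.279 for the contractile and adjusted p = 0.445 for the collagen list, so that both calls were lost.

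Matrix proteases and TGF-beta response genes did not move as lists. Of 18 proteases and inhibitors, 2 were lower and 0 higher (5 lower and 3 higher when adjusted over the list alone), with an adjusted p = 0.366 for the list. Mmp19 fell from 44.1 ± 1.49 to 37.9 ± 1.45 CPM (log2 fold change -0.22, adjusted p = 0.00847; SD, n = 4). Adamts4 was at 85.4 ± 5.45 and 75.5 ± 1.75 CPM (-0.18, 0.039), a call lost without non-irradiated I or III or any irradiated library (adjusted p up to 0.106). Mmp14 (log2 fold change 0.13, adjusted p = 0.06) was not called but passed in 8 alternatives, with adjusted p from 0.00424 without both non-irradiated I and III to 0.0462 with limma-voom, among them DESeq2 (0.0147) and the fit without non-irradiated III (0.0138). Of 13 TGF-beta response genes, 3 were higher and 2 lower (4 and 3 when adjusted over the list alone), with an adjusted p = 0.364. Smad7, an inhibitor of the pathway, rose from 86.3 ± 2.40 to 109 ± 11.9 CPM (log2 fold change 0.34, adjusted p = 0.00648), Junb from 483 ± 36.4 to 613 ± 71.7 CPM (0.35, 0.0118) and Id1 from 9.29 ± 0.297 to 11.5 ± 0.313 CPM (0.31, 0.00794). The call of Id1 was lost without both irradiated I and II (0.0557), a setting chosen after seeing the data. Tgfb1, the ligand, was at 60.4 ± 8.33 and 64.3 ± 3.29 CPM (adjusted p = 0.562).

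Cholesterol synthesis genes fell together. Of 18 tested, 12 were lower and 0 higher (15 lower when adjusted over the list alone), with log2 fold changes from -0.45 to -0.05 and a median of -0.26. Cyp51, the lanosterol demethylase, fell from 80.7 ± 3.30 to 63.9 ± 1.95 CPM (log2 fold change -0.34, SE 0.04, adjusted p = 0.000296; SD, n = 4; chromosome 5, 4081145 to 4104746). Camera gave an adjusted p = 2.5e-14, and adjusted p = 0.0413 with an estimated correlation.

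**Figure D3:**
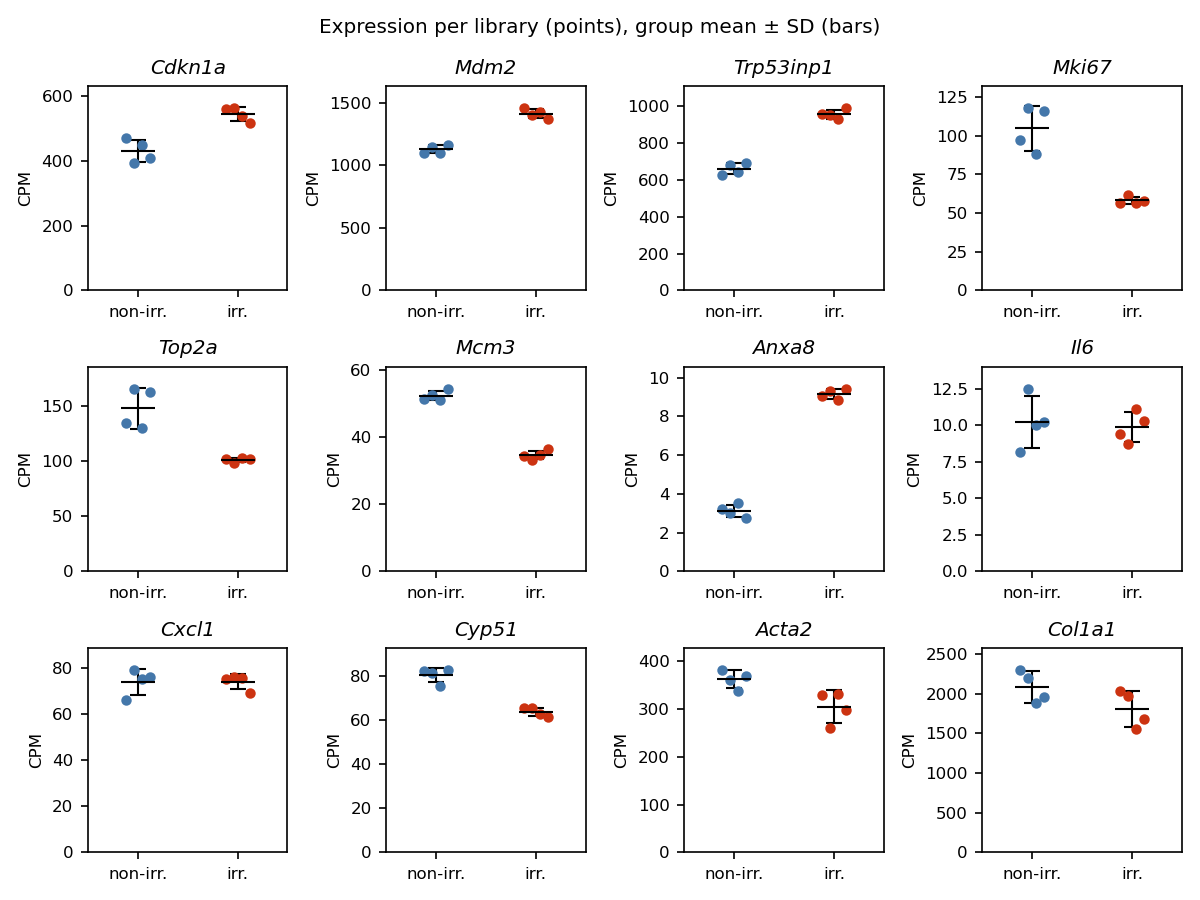
CPM (vertical axes, starting at 0) of 12 genes in each of the 4 non-irradiated and 4 irradiated libraries (points), with group mean ± SD (bars). Cdkn1a, Mdm2, Trp53inp1 and Anxa8 are higher and Mki67, Top2a, Mcm3 and Cyp51 lower in every irradiated library than in any non-irradiated one, whereas the groups overlap for Il6, Cxcl1 and Col1a1.

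The hypoxia and stress lists held more lower than higher genes. Of 18 hypoxia and glycolysis genes, 2 were lower and 0 higher, also when adjusted over the list alone (median -0.10). Hexokinase Hk2 was at 152 ± 9.11 and 131 ± 5.60 CPM (log2 fold change -0.21, adjusted p = 0.0167; SD, n = 4; 0.053 without irradiated II), and Pgk1, a glycolytic kinase, at 18 ± 5.81 and 11.6 ± 0.560 CPM (-0.63, 0.0334), a call lost without non-irradiated III or any irradiated library (adjusted p up to 0.0904). Without non-irradiated I, which was at 26.5 CPM against 13.8 to 17.1 CPM in the rest of its group, the log2 fold change of Pgk1 was -0.39. Vegfa was at 915 ± 35.4 and 927 ± 41.1 CPM (adjusted p = 0.854). Of 16 unfolded protein and integrated stress genes, 6 were lower and 1 higher (8 and 1 when adjusted over the list alone; median -0.10). The transcription factor gene Xbp1 fell from 166 ± 3.45 to 140 ± 4.78 CPM (log2 fold change -0.25, adjusted p = 0.000886) and Manf from 61.4 ± 2.95 to 51.4 ± 2.10 CPM (-0.25, 0.00389), the latter with an adjusted p = 0.0548 without both irradiated I and II. The chaperone gene Hspa5 was at 569 ± 25.1 and 513 ± 12.4 CPM (-0.15, 0.0354), a call kept in 1 of the 8 fits that leave out 1 library, that without non-irradiated I, with adjusted p up to 0.131. By camera, adjusted p = 0.00327 for the hypoxia list and 0.00624 for the stress list, and with an estimated correlation adjusted p = 0.254 and adjusted p = 0.445. The stress list also missed the threshold without non-irradiated III (0.0516), and without both non-irradiated I and III, a pair chosen after seeing the data, the hypoxia list had an adjusted p = 0.0582 and the stress list 0.161.

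Of 13 NRF2 antioxidant genes, 1 was higher and 1 lower (1 and 2 when adjusted over the list alone). The list had a median of -0.06 and an adjusted p = 0.123 by camera. It was called lower without non-irradiated II (0.0352) and without non-irradiated IV (0.0299). With both non-irradiated I and III left out, a pair chosen after seeing the data, its median was 0.02, with 2 genes higher and 0 lower. The cystine transporter gene Slc7a11 was at 55.6 ± 10.9 and 41.9 ± 2.65 CPM (log2 fold change -0.41, adjusted p = 0.0334; SD, n = 4), a call lost without non-irradiated I or any irradiated library (adjusted p up to 0.0923), with DESeq2 (0.0547) and with the GC and length trends removed (0.055). Its log2 fold change shrank to -0.17 without both non-irradiated I and III (adjusted p = 0.107). Gclc, a subunit of the glutathione-synthesis ligase, was at 85.9 ± 4.59 and 96.7 ± 3.88 CPM (0.17, 0.0452), a call kept in 2 of the 8 fits that leave out 1 library, those without non-irradiated III and without irradiated II, with adjusted p up to 0.135. Txnrd1 was not called (adjusted p = 0.545). Of 29 lysosomal genes, 3 were higher and 0 lower, also when adjusted over the list alone (median 0.03). Mcoln1, a lysosomal channel, rose from 53.3 ± 0.827 to 61.3 ± 1.67 CPM (log2 fold change 0.20, adjusted p = 0.00441) and Ctsd, cathepsin D, from 344 ± 21.4 to 395 ± 9.20 CPM (0.20, 0.0142), while Psap was at 1380 ± 132 and 1370 ± 35.3 CPM (adjusted p = 0.978). Camera gave the lysosomal list an adjusted p = 0.0355, and adjusted p = 0.6 with an estimated correlation. Its call was also lost without non-irradiated II (0.418), non-irradiated IV (0.195) or irradiated III (0.0527). The rise of the list was instead larger without both non-irradiated I and III, with a median of 0.11 and 7 genes higher and 0 lower. Without both irradiated I and II, adjusted p values were 0.102 for Mcoln1 and 0.08 for Ctsd.

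Of 27 interferon-stimulated genes tested, 3 were higher and 0 lower (7 higher when adjusted over the list alone), with a median of 0.09. Ifit1 rose from 282 ± 28.5 to 366 ± 31.5 CPM (log2 fold change 0.38, adjusted p = 0.00565; SD, n = 4) and Mx2 from 45.5 ± 3.79 to 54.7 ± 2.33 CPM (0.27, 0.0125), while Ifitm3 was at 420 ± 32.4 and 376 ± 30.9 CPM (-0.16, 0.152). Ifitm3 passed without the low-count filter (0.0084) at the same log2 fold change, although its groups overlapped. Camera gave an adjusted p = 0.00418, and adjusted p = 0.6 with an estimated correlation. The call of the list was also lost without non-irradiated II (0.184) or irradiated II (0.0681), and without both irradiated I and II the list had 0.0745 and Mx2 0.0579. Of 13 genes of MHC class I antigen presentation, 1 was lower and 0 higher, also when adjusted over the list alone. This was the peptidase gene Erap1, at 42.9 ± 1.01 and 38.3 ± 0.740 CPM (log2 fold change -0.16, adjusted p = 0.0207), a call lost without non-irradiated IV or any irradiated library (adjusted p up to 0.0881). B2m was at 402 ± 24.4 and 414 ± 14.3 CPM (adjusted p = 0.659) and H2-Q4 at 23.1 ± 2.79 and 24.9 ± 1.34 CPM (adjusted p = 0.47). The MHC class I list had an adjusted p = 0.904 by camera, with a median of 0.02 and a mean that rounds to 0.

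Markers of epithelial, leukocyte, endothelial, glial, mesothelial and Cajal cells were at 21.3 CPM or lower, while smooth muscle and pericyte markers reached 334 CPM (Actg2). The highest group mean was 3.75 CPM among 14 epithelial markers (Lgals4), 0.724 CPM among 13 macrophage and leukocyte markers (Csf1r) and 21.3 CPM among 12 endothelial markers (Flt1). It was 0.0964 CPM among 6 mesothelial markers (Msln) and 9.29 CPM among 3 markers of interstitial cells of Cajal (Etv1). None of the 7 enteric glia markers reached 1 CPM, and no tested member of these lists was called. Of 8 tested smooth muscle and pericyte markers, Notch3 (log2 fold change 0.27, adjusted p = 0.0109) and Synpo2 (0.33, 0.0134) were higher and Actg2 was lower (334 ± 10.1 and 291 ± 21.1 CPM, adjusted p = 0.0263; SD, n = 4). The call of Actg2 was lost without any 1 of non-irradiated I, II and IV and irradiated II and IV (adjusted p up to 0.0987). Of 11 fibroblast identity markers, Col1a2 (log2 fold change -0.24, adjusted p = 0.0101) and Vim (-0.14, 0.0462) were lower. The call of Vim was kept in 1 of the 8 fits that leave out 1 library, that without irradiated III, with adjusted p up to 0.154.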

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

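Tests of the mitochondrial rRNA load, of other cell types and of the kinds of rRNA in irradiated I and II were chosen after the results they bear on were seen. In each group of 4 libraries, the highest and lowest values of named genes, list medians and library measures were compared with the rest of the group, and 12 of 220 such comparisons had 1 library far from the other 3, where chance gives about 11 (1 in 20 groups). Cpz was at 2.90 CPM in non-irradiated III against 3.56 to 3.62 CPM in the rest of its group, and Iqgap3 at 20.5 CPM in the same library against 23.7 to 24.1 CPM. Col3a1 was at 7260 CPM in non-irradiated II against 5580 to 5850 CPM. In irradiated I, Brca1 was at 19.6 CPM against 17.7 to 18 CPM and Postn at 813 CPM against 780 to 783 CPM. Dclre1c was at 16.7 CPM in irradiated II against 14.3 to 14.6 CPM, and Erap1 at 37.2 CPM in the same library against 38.6 to 38.8 CPM. Cxcl1 was at 69.0 CPM in irradiated IV against 75.0 to 75.9 CPM. Among list medians, relative to the non-irradiated mean on the log2 scale, end-joining genes were at 0.03 in irradiated II against -0.02, SASP and NF-kB factors at -0.08 in irradiated IV against 0.01 to 0.02, unfolded protein and stress genes at -0.03 in irradiated III against -0.12 to -0.11, and lysosomal genes at 0.06 in irradiated III against 0.03.

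For the fall of G2/M and mitosis genes, with each library's trend on GC content and transcript length removed, 35 of the 35 members were still called lower, which argues against such a trend as the cause. Without irradiated I and II, the libraries with high mitochondrial rRNA, the list median was -0.62 against -0.65 with all libraries, which argues against that load. Among 55 markers of epithelial, leukocyte, endothelial, glial, mesothelial and Cajal cells the largest rise was 0.81 CPM (Lgals4), which argues against RNA of those cells diluting the list. Smooth muscle and pericyte markers, which were outside that test, went both ways, with Notch3 16.6 CPM higher and Actg2 lower (334 and 291 CPM). A dilution by such cells would lower, along with the list, those fibroblast genes that the cells lack. The 11 fibroblast identity markers had a median of -0.12 (lowest -0.36). This argues against such a dilution as the whole cause only so far as those cells lack these markers, which was not tested. Of the 35 splits of the 8 libraries into 4 and 4 only the real one gave a camera p as small. The camera p was 1.53e-44 for the real split and 6.29e-21 for the smallest of the others. All other splits mix both groups, and 1 of 35 is the smallest share possible, so the splits do not decide the cause. The irradiation that the design names stays open and was not itself tested as the cause.

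For the lower matrix and contractile genes, 40 genes of both lists had a median log2 fold change of -0.14, and -0.13 after the GC and length trends were removed, a ratio of 0.94, which argues against those trends as the cause. Chance cannot be excluded for the contractile list: 6 of the 35 splits, the real one included, gave a camera p as small, with 1.43e-09 as the smallest among the others against 1.22e-05 for the real split. The irradiation the design names stays open and was not separated from chance.

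Mitochondrial rRNA was at least 2.55 times higher in irradiated I and II than in any other library. Mitochondrial coding transcripts did not rise with it, since the lower of both libraries was at 0.88 times the highest of the other 6, which argues against more mitochondrial RNA of all kinds. The comparison covers only the counted reads of 13 coding genes. Together they held 1977 to 2648 CPM per library, and 7 of them passed the low-count filter. Carry-over of rRNA of all kinds cannot be told apart from a change in mitochondrial rRNA alone: nuclear genes annotated as rRNA were at 2.23 times the highest other library in irradiated II but at 1.06 times in irradiated I, and Gm26917, a locus with rRNA sequence that was looked at first, was at 0.72 times in the lower of both. The counts of the nuclear rRNA genes came almost wholly from 1 locus, CT010467.1. It was at 945 and 1995 CPM in irradiated I and II and at 113.7 to 882 CPM in the other 6 libraries. Irradiated III and IV had the same treatment without the rise in mitochondrial rRNA, and no biological explanation was tested. The call of mt-Rnr1 (log2 fold change 1.78, SE 0.50, adjusted p = 0.0492 by edgeR) rests on irradiated I and II and was lost without either of them or any 1 non-irradiated library (adjusted p up to 0.139).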

How the results depend on the processing

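Removing the GC and length trends and leaving out pairs of libraries were chosen after seeing the data. Of 74 recomputed gene counts, 56 stayed within 1.5 times and 18 moved further. The higher count of 395 became 648 without a filter, 140 at a threshold of 0.01 and 608 with the GC and length trends removed, and the lower count of 634 became 296 at 0.01 and 295 without both irradiated I and II. At 2-fold, the 22 higher genes became 14 with DESeq2, 51 without a filter, 12 with at least 1 CPM in 4 libraries, 34 without both irradiated I and II and 12 without both non-irradiated I and III, and the 7 lower genes became 14 without a filter and 30 without both non-irradiated I and III. The filters change which genes are tested and the pairs leave fewer samples. The cause of the other shifts was not tested. Leaving out 1 library gave 221 to 402 higher and 415 to 611 lower genes, and 15 to 26 and 4 to 16 at 2-fold. Each fit called 0 of the 1029 genes in the opposite direction, and DESeq2 shared 96.3% and the pair without irradiated I and II 45.6% of them. Of 288 recomputed list tests, 264 kept their side of the threshold, 22 lost the call, 2 gained it and 0 reversed. With an estimated correlation, adjusted p = 0.161 for recombination and Fanconi genes, 0.0504 for G2/M, 0.279 for contractile, 0.445 for collagens, 0.6 for interferon-stimulated, 0.254 for hypoxia, 0.445 for stress and 0.6 for lysosomal genes, so 3 of the 11 calls were kept. With fry, collagens had 0.0586 and interferon-stimulated and lysosomal genes 0.237 each. Without both irradiated I and II, interferon-stimulated genes had 0.0745, stress genes 0.0785 and lysosomal genes 0.0711. Without both non-irradiated I and III, hypoxia genes had 0.0582 and stress genes 0.161. Leaving out 1 library gave adjusted p from 0.000123 to 0.184 for interferon-stimulated genes, 0.000976 to 0.0516 for stress genes, 0.00102 to 0.418 for lysosomal genes and 0.0299 to 0.428 for NRF2 genes. Of 58 named genes called, 47 kept the call in each of the 8 fits that leave out 1 library, and no named gene reversed. The pair without irradiated I and II ended 17 calls of named genes and the pair without non-irradiated I and III 7. Whether the replicate numerals pair the libraries is not settled. Same-numbered libraries had correlations of their deviations of 0.02, -0.03, 0.27 and 0.15, and 2 of the 4 numerals had their highest correlation with themselves. A fit with the replicate block called 550 higher and 802 lower genes, 25 and 7 at 2-fold, changed no list call and added calls of Lmnb1 (adjusted p = 0.0484) and Col1a1 (0.00456). A change of the low-count filter alone moved the 22 higher genes at 2-fold to 51 and to 12. Whether depth limits genes under about 1 CPM was not tested.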

Other observations

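The genes and families in this paragraph and the next were chosen after their values were seen, as was the test of the G2/M against the G1/S list. Of 48 replication-dependent histone genes tested, 24 were lower in irradiated cells, 3 were higher and 21 were not called, and no list test was run on them. They had a median log2 fold change of -0.36 under TMM, RLE and upper-quartile factors alike. Hist1h1e fell from 192 ± 19.9 to 129 ± 9.38 CPM (SD, n = 4; log2 fold change -0.57, adjusted p = 0.000169 by edgeR), and Hist1h1b fell with a log2 fold change of -0.61 (0.000168). Hist3h2a rose from 9.10 ± 1.11 to 13.4 ± 0.660 CPM (0.56, 0.00111). Histone genes share sequence with one another, and most lack a poly(A) tail. Rn7sk, a small nuclear RNA also made without such a tail, was at 4576 to 8031 CPM in these libraries despite the polyA label.

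Some called genes work in serine, one-carbon and amino acid metabolism. They were picked because they were called, and no list of such genes was tested. Aldh1l2, a mitochondrial folate enzyme, fell from 50.2 ± 4.11 to 31.5 ± 1.65 CPM (SD, n = 4; log2 fold change -0.67, adjusted p = 2.89e-05 by edgeR). Psat1 and Phgdh of the serine pathway fell with log2 fold changes of -0.47 (4.19e-05) and -0.43 (0.0102), Mthfd2 with -0.35 (0.00152), Shmt2 with -0.26 (0.00377), Bcat1 with -0.40 (3.22e-05) and the asparagine synthetase gene Asns with -0.24 (0.0138). Serpine2, a protease inhibitor, rose from 94.4 ± 2.93 to 146 ± 1.69 CPM (0.63, 1.33e-06), and Abca8b, a relative of Abca8a, from 13.1 ± 1.15 to 21.8 ± 0.777 CPM (0.73, 3.19e-05). The mitotic transcription factor gene Foxm1 fell from 12.4 ± 1.44 to 7.07 ± 0.433 CPM (-0.81, 0.000117).

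A hypothesis that the G2/M list fell further than the G1/S list was tested on the difference of both medians in each library. The difference changed from 0.01 ± 0.09 to -0.30 ± 0.07 (SD, n = 4) on the log2 scale, and an exact two-sided permutation test over 70 assignments gave p = 0.0286, the smallest p this design can give. The difference in fall may therefore go beyond the spread between these libraries, as a hypothesis noticed and tested on the same data.

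Other splits of the 8 libraries into 4 and 4 were fitted in the same way. Of the 35 splits, only 1, the real one, gave as many as 395 genes in one direction and 634 in the other, and only 1 gave 22 and 7 genes at 2-fold. The highest count in any other split was 0 in each case. The real split therefore stands apart, but 1 of 35 is the smallest share that this test can give. All other splits mix irradiated with non-irradiated libraries, which adds any difference between the groups to their spread. The labels do not say whether the libraries came from separate cultures, so a chance difference between cultures cannot be excluded by these splits. For the number of lists called by camera at the preset correlation chance is not excluded: 3 of the 35 splits, the real one included, called as many as the real 11, and the highest of the other splits was also 11. Those were the split that exchanges non-irradiated IV with irradiated I and the split that sets non-irradiated I with irradiated I, II and IV. With an estimated correlation, the real split called 3 lists and each other split 0, though the other splits mix both groups. For single lists, the real split alone had the smallest camera p for p53 targets, recombination and Fanconi genes, G1/S genes, G2/M genes and cholesterol synthesis genes, while 16 of the 35 splits had a p as small for interferon-stimulated genes, 15 for lysosomal genes, 5 for collagens, 5 for stress genes and 4 for hypoxia genes.

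Some genes differed between irradiated libraries more than between the groups. Cebpb, a transcription factor gene, was at 66.0 and 79.3 CPM in irradiated I and II and at 151 and 184 CPM in III and IV, against 46.1 to 79.0 CPM in non-irradiated libraries, and its call (log2 fold change 0.99, adjusted p = 0.0419 by edgeR) was lost without any 1 of non-irradiated I, II and IV and irradiated III and IV (adjusted p up to 0.135). Scand1 was at 6.11 and 9.67 CPM in irradiated I and II and at 31.1 and 35.9 CPM in III and IV. Lars2 was at 119 and 495 CPM in irradiated I and II and at 11.7 to 27.9 CPM in the other 6 libraries (adjusted p = 0.0694). Irradiated I and II were also the libraries with high mitochondrial rRNA, and whether the rise of Lars2 belongs with that load was not tested. The first principal component, with 27.1% of the variance, set non-irradiated I and III, at -23.3 and -19.9, apart from the other 6 libraries, at 0.7 to 16.1.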
